A study of Mus musculus with 18 samples.

How the data were processed

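According to the labels, RNA came from endothelial cells of mouse heart and liver, was captured as poly(A) RNA, copied into full-length cDNA from an oligo(dT) primer, amplified by PCR and read as paired 100 bp reads on an MGISEQ-2000RS. The submitters' processing notes name the genome build as mm10. The aligner, the program that counted reads and the gene annotation were not given in the sources used here. The labels name no batch, date, animal number or sort day for a library.

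Per the file headers, each tissue has 1 table with a TPM column and a read count column for each library. The deposited TPM values were scaled by the authors for gene length and depth, per the file headers. The deposited counts are the authors' expected counts, estimated per gene and not normalized, per the file headers and the values. The heart table held 17513 genes in 12 libraries, and that of the liver held 17242 genes in 6 libraries. All 36 per-library columns were matched to a sample by name, with 0 left over. Between 80.8% and 83.5% of the deposited heart counts and between 80.3% and 80.8% of the liver counts per library, zeros included, were exactly whole (no tolerance); the counts were rounded before any test. TPM values were not used for tests. The 4th heart region is written OR in the sample titles and OZ in the columns of the count table, and it is called OR throughout. The heart and liver tables were never compared with each other, since they came from separate runs of the authors' processing and from mice of different genotype.

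Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by edgeR's default filter, library sizes were scaled by the trimmed mean of M values (TMM), and quasi-likelihood F tests with robust dispersion were run on a model with 1 mean per group. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. The heart model held all 12 libraries and gave 1 test over the 4 regions and 1 test for each of the 6 pairs of regions; the liver model held all 6 libraries. A gene counted as distinct to a region when it passed in all 3 pairs with that region and moved the same way in each. Fold changes are log2 values of the first named group over the second. Their standard error (SE) was derived from the test, as the size of the log2 fold change over the square root of its F statistic. Group levels are CPM scaled by TMM, as mean ± SD of 3 libraries. P-values of this kind measure only the spread between these libraries, because nothing in the labels says that replicates of a group came from separate animals, nor whether libraries with the same number came from the same one.

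Gene lists were written from general knowledge of heart and liver cell types and of endothelial programmes, 39 for the heart and 42 for the liver, and 37 and 41 of them had enough measured members to be tested. They were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2, once with the preset correlation between genes of 0.01 and once with a correlation estimated from the libraries, and with fry. List p-values were adjusted over the lists of a comparison. For single members, the count is given over all genes tested and adjusted over the list alone.

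Genes were named by a fixed rule. For each heart pair these were the 5 genes with the largest change in each direction among those past the threshold, with a log2 fold change of at least 1 either way, a mean of at least 5 CPM in the higher group and no overlap between the groups; for the liver the number was 15 in each direction. For a region, up to 8 distinct genes in each direction were taken, and for the test over the 4 regions the 10 with the smallest p. Where no gene qualified, the 5 with the smallest p at that level were named and are said not to have passed. Up to 4 members of each list described, and Mki67, Top2a, Pecam1, Cdh5, Kdr and Ptprc in both tissues, were named whatever their values. Unnamed transcript models and pseudogenes were counted but not named. The comparisons, the tests, the threshold, the lists, this rule and the alternative settings, among them a fit on the 6 libraries of each heart pair alone, were fixed before the data were examined. Voom with sample quality weights, the naming rule and the regroupings applied to the pairs alone, and the naming rule applied after leaving out 1 library, were added once the spread between libraries had been seen.

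DESeq2 1.42.0, a model with the replicate number as a block, other filters and scaling, and the omission of each library in turn were run as alternatives. The workflow was tested on simulated data with the depth and dispersion of these tables, in which 67 genes each were changed 1.5-fold and 2-fold and 66 genes 4-fold. For a heart pair the edgeR model recovered 4.48%, 44.8% and 71.2% of them, and for the liver 2.99%, 23.9% and 72.7%, with 0 calls in the wrong direction and 4 and 6 calls among unchanged genes. The simulation drew each gene independently and held no shift of a whole library. These shares may therefore overstate recovery in the real tables, and 0 calls there do not show that large differences are absent. Gene positions are from the RefSeq annotation of GRCm38.p6 (mm10), matched by the gene identifier that the deposited tables give beside each symbol. In that annotation 17461 of the heart identifiers and 17193 of the liver identifiers were found. Plots were drawn with matplotlib 3.10.9 from Python 3.11.15.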

Results

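RNA was sequenced from endothelial cells, the cells that line blood vessels and heart chambers, of 2 mouse organs. The heart set held 12 libraries of wild-type adult males under resting conditions. They came from 4 regions that the labels call Apex, LV, VS and OR, with 3 libraries each. The liver set held 6 libraries from mice with 2 recombinases, Ki67-CrexER under the proliferation gene Mki67 and Cdh5-DreER under the endothelial gene Cdh5, and the red reporter R26-RL-tdT. Of these, 3 were of tdTomato-positive and 3 of tdTomato-negative endothelial cells. Total counts per library ranged from 21590400 to 27720154 in the heart and from 23715769 to 26538590 in the liver.

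Endothelial genes were abundant in both sets. Pecam1 and Cdh5, adhesion molecules of endothelial junctions, were at 2018 ± 207 (SD, n = 3) and 2928 CPM in Apex. They were at 1751 and 2701 CPM in LV, 1726 and 2728 in VS, and 1793 and 2759 in OR. Ptprc, the pan-leukocyte gene that encodes CD45, lay between 0.547 CPM in OR and 1.22 CPM in LV. In the liver, Pecam1 was at 993 CPM in positive and 1037 CPM in negative libraries, and Cdh5 at 627 and 652 CPM. Ptprc was at 20.6 CPM in positive libraries and at 0.717, 1.60 and 48.7 CPM in the 3 negative libraries.

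The comparison of the 4 heart regions asks whether resting endothelial cells differ in expression by their place in the heart. Slit3, a secreted guidance ligand, had the smallest p and its highest mean in LV (9.62 ± 1.45 CPM, SD, n = 3). Myl7, the atrial myosin light chain, was nearly absent from Apex (0.0497 CPM). Chil3, a chitinase-like protein of myeloid cells, was highest in Apex (5.24 ± 1.10 CPM), and C4b, a complement component, in LV (5.48, 4.39 and 7.36 CPM). All 4 had an edgeR quasi-likelihood adjusted p of 0.144 and so did not pass. The next by p were Spock2, an extracellular proteoglycan, and Pgf, a ligand of the VEGF receptor Flt1 (both 0.187 by edgeR). Then came Cry1, a repressor of the circadian clock (0.267), and Mpo, Hoxb5 and C7 (0.317 by edgeR). Mpo, the granule peroxidase of neutrophils, had 33, 22 and 23 counts in the Apex libraries and 0 in the other 9. With 3 counts over a group as the floor, it was at least 24.9-fold higher in Apex than in LV, 24.3-fold than in VS and 23.3-fold than in OR. Hoxb5, a positional transcription factor, was at 3.39 CPM in Apex, 3.84 in LV, 0.774 in VS and 4.31 in OR. Floors of this kind cover counting error only.

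Of 13542 genes tested over the 4 regions with edgeR, 0 passed an adjusted p of 0.05, with 1084 at an unadjusted p under 0.05. DESeq2 called 87 and voom with sample quality weights 2908. Without VS 1, edgeR called 1481 genes. VS 1 was picked because its omission changed the calls most, and it leaves only VS 2 and VS 3 in that region. This count and all later calls and p-values without VS 1 carry that choice. Without LV 2 edgeR called 2, Upk3b, a marker of mesothelium, and Chil3, both looked up after the count was known. VS 1 stood apart from VS 2 and VS 3 in the level of ribosomal protein genes (7.94 against 9.12 and 9.03 log2 CPM). Cardiomyocyte genes (5.43 against 7.63 and 6.99) and oxidative phosphorylation genes (6.59 against 7.72 and 7.48) were lower in it too. In the plot of principal components, the first component held 22.2% of the variance and ran from VS 1 to VS 2, libraries of the same region.

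**Figure D1:**
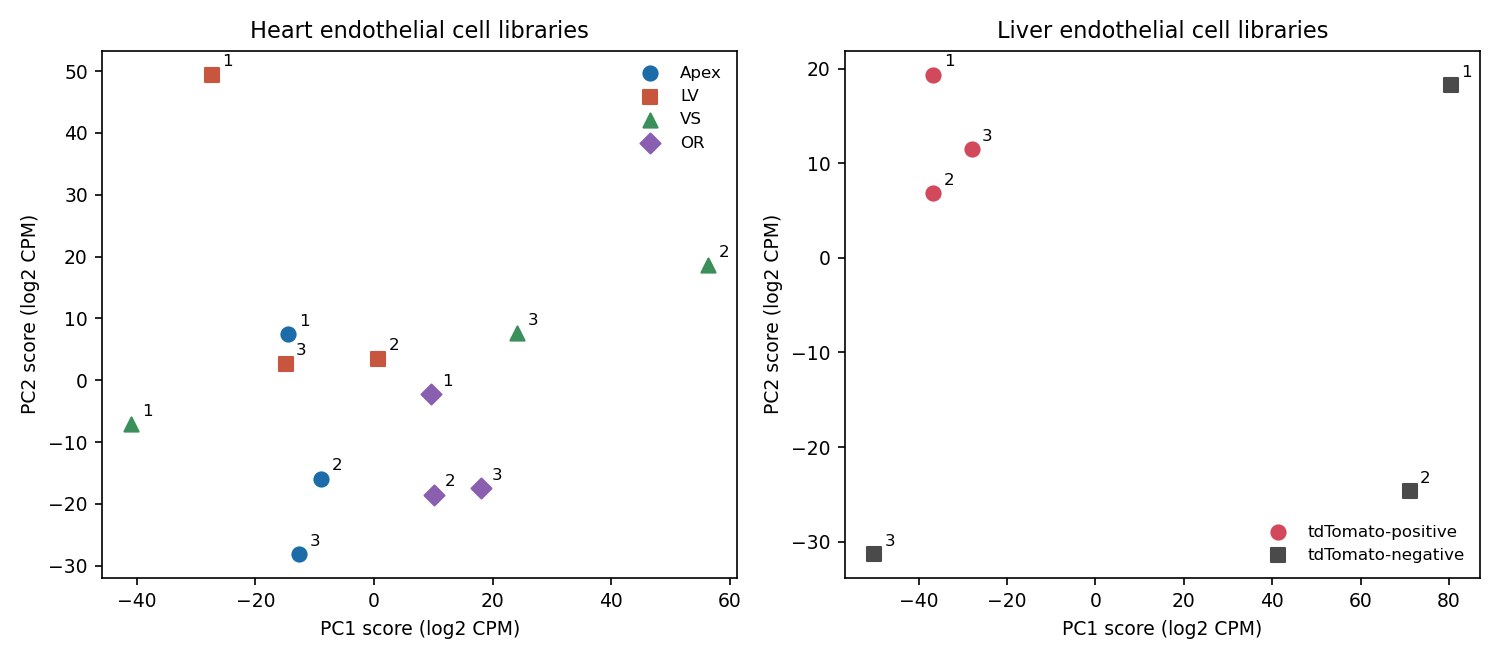
Scores of each library on the first (x) and second (y) principal component of log2 CPM, for the heart (12 libraries, coloured by region) and the liver (6 libraries, coloured by reporter), with replicate numbers beside the points. VS 1 and VS 2 lie at opposite ends of the heart's first component (22.2% of the variance), and liver negative 3 lies with the positive libraries on the liver's first component (73.2%).

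Gene lists were also compared between regions. With camera's preset correlation, 46 list comparisons of the heart passed. With an estimated correlation 0 did, fry gave 2, and an exact permutation of the levels of 37 lists over the 4 regions gave 0, with 6 at an unadjusted p under 0.05. Lists that passed with the preset correlation are therefore given with their adjusted p under an estimated correlation.

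In Apex against LV, the proliferation gene Mki67 was higher in Apex, and Myl7, Nppa and Sln, transcripts of atrial heart muscle, were higher in LV, in the fit on these 6 libraries alone. Mki67, a nuclear protein of cycling cells, was at 22.2 ± 0.805 CPM in Apex and 10.1 ± 1.84 CPM in LV (SD, n = 3). Its log2 fold change was 1.15 ± 0.16 (SE, 2.22-fold, edgeR adjusted p 0.0272). Npr3, the natriuretic peptide clearance receptor, was 2.98-fold higher in Apex (9.62 ± 1.49 against 3.23 ± 0.754 CPM, edgeR adjusted p 0.0493). Angptl4, an inhibitor of lipoprotein lipase, was 2.33-fold higher (69.9 ± 13.6 against 30.1 ± 4.68 CPM, edgeR adjusted p 0.0272). Slit3 was 3.07-fold lower in Apex (3.12 ± 0.0912 against 9.62 ± 1.45 CPM, 0.0272 by edgeR). Nppa, the atrial natriuretic peptide, was 4.61-fold lower (2.96 ± 0.621 against 13.7 ± 3.41 CPM, 0.0133 by edgeR). Myl7 was 168-fold lower, from 3, 0 and 1 counts in Apex against 354, 159 and 201 in LV (0.00128 by edgeR). Ccn5, a matricellular protein, and Syn3, a synapsin, also qualified as lower, at 2.03 against 8.23 and 10.7 against 25.4 CPM. Sln, which encodes the calcium pump regulator sarcolipin, had 0 counts in all 3 Apex libraries. It was at least 86.7-fold higher in LV, with 3 counts over the group as the floor.

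That fit called 20 genes, 4 higher and 16 lower in Apex, of 13169 tested. With all 12 libraries in the model, edgeR called 0 genes between Apex and LV, with 728 at an unadjusted p under 0.05. DESeq2 called 24 (9 higher and 15 lower in Apex) and voom with sample quality weights 38 (10 and 28). The smallest edgeR adjusted p-values over all libraries were 0.0733 for Myl7 and 0.0749 for Slit3. Prkcq, a protein kinase C (8.50 against 3.95 CPM), C4b (1.32 against 5.75 CPM) and Dkk3, a secreted Dickkopf protein (2.53 against 10.5 CPM), followed at 0.402 by edgeR, and Mki67 was at 0.930. Leaving out VS 1 brought Slit3 past the threshold (0.0310 by edgeR). Leaving out VS 3, OR 1 or OR 2 did so for Myl7 (0.0184, 0.0465 and 0.00717 by edgeR), each time as the only gene. All 22 genes of mitosis were higher in Apex, with a median log2 fold change of 0.88 (camera adjusted p 6.6e-18, adjusted p = 0.179 with an estimated correlation). In the fit on the pair only Mki67 passed over all genes, and 17 passed adjusted over the list alone (adjusted p = 0.284 with an estimated correlation). None of 23 genes of DNA replication passed in that fit, also adjusted over the list alone (median 0.20, adjusted p = 0.623 with an estimated correlation). All 8 atrial cardiomyocyte genes were lower in Apex, with a median of -1.75 (camera 1.3e-11, fry 0.00853, adjusted p = 0.113 with an estimated correlation). In the fit on the pair, Sln, Myl7 and Nppa passed over all genes and 6 adjusted over the list alone (adjusted p = 0.284 with an estimated correlation), while with all libraries 0 passed over all genes and 5 adjusted over the list alone. In the fit on the pair, fibroblast genes had a median of -0.71 and 0 passed, also adjusted over the list alone (camera 7.6e-04, adjusted p = 0.753 with an estimated correlation). With all regions in the model and LV 3 left out, it was -0.19 (camera 0.138). Neutrophil genes had a median of 2.12 in the fit on the pair, and 5 of 7 passed as higher adjusted over the list alone (camera 0.0146, adjusted p = 0.623 with an estimated correlation). With all libraries, interferon response genes had a median of 0.31 (adjusted p = 0.179 with an estimated correlation). On build mm10, Npr3 lies on chr15 at 11839896-11907837, Angptl4 on chr17 at 33774900-33781575 and Mki67 on chr7 at 135689784-135716450. Myl7 lies on chr11 at 5896637-5898782, Nppa on chr4 at 148000722-148002074 and Slit3 on chr11 at 35121456-35708507.

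In Apex against OR, the cell division genes Mki67, Top2a and Kif11 were higher in Apex, and most ribosomal protein and respiration genes and some cardiomyocyte genes were lower, in the fit on these 6 libraries alone. Mki67 was 3.11-fold higher (22.2 ± 0.805 against 7.19 ± 2.72 CPM, SD, n = 3, edgeR adjusted p 0.0128). Top2a, the topoisomerase that untangles replicated DNA, was 2.60-fold higher (24.0 ± 3.70 against 9.29 ± 1.86 CPM, edgeR adjusted p 0.0128). Kif11, the kinesin that separates spindle poles, was 2.56-fold higher (6.15 against 2.41 CPM, 0.0193 by edgeR). Chil3, which has the close relative Chil4, was 21.4-fold higher in Apex (edgeR adjusted p 0.0144), from 175, 126 and 127 counts against 0, 15 and 3. Lrrn1, a leucine-rich repeat membrane protein, was at 11.6 against 3.72 CPM. Plac9a, a small secreted protein with near-identical copies, was lower in Apex (13.3 against 29.4 CPM). So was G0s2, an inhibitor of the triglyceride lipase Pnpla2 (6.71 against 14.8 CPM).

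The fit on Apex and OR alone called 956 of 13099 genes, 398 higher and 558 lower in Apex, and 15 met all criteria for naming. With all 12 libraries edgeR called 0, with 1642 at an unadjusted p under 0.05. The genes named above had edgeR adjusted p-values of 0.376 to 0.379 there. DESeq2 called 47 (44 and 3), voom with sample quality weights 1793 (788 and 1005), and edgeR without VS 1 called 860 (328 and 532). The smallest p over all libraries belonged to Slc25a28, a mitochondrial iron importer (14.1 against 27.7 CPM), and Cry1 (38.9 against 24.3 CPM). Ifi44, an interferon-induced gene (64.9 against 39.6 CPM), Tlr4, the endotoxin receptor (26.7 against 14.2 CPM), and Megf9, a membrane protein (log2 fold change 0.75), came next, none past the threshold. Ribosomal protein genes were lower in Apex in 25 of 25 cases (median log2 fold change -0.57, camera 5.2e-10, adjusted p = 0.657 with an estimated correlation). In the fit on the pair, 21 of them passed over all genes and 25 adjusted over the list alone (adjusted p = 0.716 with an estimated correlation). Of 26 nuclear genes of oxidative phosphorylation, 15 passed as lower over all genes and 21 adjusted over the list alone in the same fit (median -0.47, adjusted p = 0.716 with an estimated correlation). Cardiomyocyte genes were lower in that fit too, with 6 of 15 past over all genes (Cox6a2, Mb, Myl3, Myl2, Tnni3 and Tnnc1) and 8 adjusted over the list alone (median -0.55, adjusted p = 0.716 with an estimated correlation). Of 22 mitosis genes, 7 passed as higher (Cenpf, Top2a, Kif11, Mki67, Prc1, Cenpe and Tpx2) and 14 adjusted over the list alone, again in the fit on the pair (median 0.78, adjusted p = 0.716 with an estimated correlation). With all libraries 1 mitosis gene passed adjusted over the list alone (median 0.77, camera 5.2e-10, adjusted p = 0.657 with an estimated correlation), and 0 genes of the oxidative phosphorylation list did (median -0.49, adjusted p = 0.680 with an estimated correlation). Of 23 interferon response genes, Ifi44, Rsad2, Ifit2, Stat2 and Gbp7 passed as higher in Apex, and adjusted over the list alone 8 passed as higher and 1 as lower (camera 0.0485, adjusted p = 0.716 with an estimated correlation). Of 17 heart capillary genes, Tcf15, Gpihbp1, Fabp5 and Car4 passed as lower and Btnl9 as higher, and the list did not pass (camera 0.0955). Top2a lies on chr11 at 98992947-99024199, Kif11 on chr19 at 37376382-37421863 and Chil3 on chr3 at 106147554-106167564.

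In LV against OR, the complement gene C4b and the collagen gene Col14a1 were higher in LV, and Npr3, the platelet gene Pf4 and Hbb-bs were higher in OR, in the fit on these 6 libraries alone. With all 12 libraries none of them passed (edgeR adjusted p 0.131 to 0.416). C4b, which has the close relative C4a, had a log2 fold change of 2.81 ± 0.36 (SE, n = 3, edgeR adjusted p 0.0204 in the fit on these 6 libraries). Its mean was 5.75 CPM in LV and 0.818 ± 0.248 CPM in OR. Wdfy1, an adaptor of endosomal Toll-like receptors, was at 24.2 ± 1.46 against 8.69 ± 1.32 CPM (SD, n = 3, edgeR adjusted p 0.00625). Trps1, a GATA-type repressor, was at 13.9 against 5.01 CPM, and Col14a1, a fibril-associated collagen, at 8.16 against 3.02 CPM. Ackr2, a chemokine scavenger, was at 6.79 against 2.52 CPM. Npr3 was 3.26-fold lower in LV (3.23 ± 0.754 against 10.6 ± 0.547 CPM, edgeR adjusted p 0.0204). Ctsh, a lysosomal cysteine protease, was 2.93-fold lower (6.35 against 18.7 CPM) and Pf4, a platelet chemokine, 2.51-fold lower (3.24 against 8.19 CPM). Hbb-bs, an adult beta-globin with near-identical copies, was at 413.8 ± 115 CPM in LV and 863 ± 53.4 CPM in OR (0.0253 by edgeR).

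The fit on LV and OR alone called 462 of 13098 genes, 236 higher and 226 lower in LV, of which 22 met all criteria for naming. With all 12 libraries edgeR called 0, with 1564 at an unadjusted p under 0.05 and a smallest adjusted p of 0.131, for C4b and Cry1. DESeq2 called 49 (34 and 15), voom with sample quality weights 380 (226 and 154), and edgeR without VS 1 called 375 (173 and 202). Cry1 was at 42.8 against 24.3 CPM and Spock2 at 26.1 against 12.7 CPM. Hspa4l, a heat-shock chaperone, was at 27.8 against 13.7 CPM, and Oas2, an interferon-induced sensor of viral RNA, at 84.5 against 51.2 CPM. Ribosomal protein genes were lower in LV in 25 of 25 cases (median log2 fold change -0.47, camera 1.0e-07, adjusted p = 0.702 with an estimated correlation). In the fit on the pair, 11 of them passed over all genes and 24 adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Of 26 oxidative phosphorylation genes, 6 passed as lower over all genes in that fit and 16 adjusted over the list alone (adjusted p = 0.694 with an estimated correlation). Of 12 erythrocyte and platelet genes, 5 and 7 did (adjusted p = 0.694 with an estimated correlation). Of 15 cardiomyocyte genes in the same fit, Mb, Myl3, Myl2, Tnni3 and Tnnc1 passed as lower over all genes and 7 adjusted over the list alone (median -0.31, adjusted p = 0.816 with an estimated correlation). With all libraries 0 genes of the oxidative phosphorylation and cardiomyocyte lists passed adjusted over the list alone. With all libraries, atrial cardiomyocyte genes were higher in LV in 8 of 8 cases (median 1.32, camera 5.5e-05, adjusted p = 0.696 with an estimated correlation). Fibroblast genes had a median of 0.57 in the fit on the pair, with 0 past adjusted over the list alone (camera 0.0147, adjusted p = 0.816 with an estimated correlation). Lymphatic genes had one of 0.74, with Mmrn1 past over all genes (camera 0.00191, adjusted p = 0.694 with an estimated correlation). C4b lies on chr17 at 34728139-34743902, and Wdfy1 on chr1 at 79702262-79776143.

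In Apex against VS, the vessel-growth ligands Pgf and Apln had higher means in Apex, and the proliferation gene Mki67 passed as higher by edgeR only without VS 1. Pgf was at 41.1 ± 7.06 against 21.7 ± 0.657 CPM (SD, n = 3, edgeR adjusted p 0.324). Apln, the ligand of the apelin receptor and a marker of sprouting tips, was at 82.3 ± 25.1 against 40.1 ± 7.63 CPM (0.458 by edgeR). Tmem182, a muscle membrane protein, was at 71.0 against 39.2 CPM, and Spock2 at 13.7 against 25.9 CPM. Chil3 had 175, 126 and 127 counts in Apex, against 3 in VS 1 and 0 in VS 2 and VS 3. Mki67 was at 25.2 CPM in VS 1, above every Apex library, and at 2.18 and 4.48 CPM in VS 2 and VS 3. Without VS 1, which was picked by its effect on the calls, Mki67 was 6.69-fold higher in Apex (log2 fold change 2.74, edgeR adjusted p 7.4e-04). With VS 1 the fold was 2.08 (0.693 by edgeR).

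With all libraries edgeR called 0 genes between Apex and VS (1011 at an unadjusted p under 0.05), and also 0 in the fit on these 6 libraries. DESeq2 called 19 (15 and 4) and voom with sample quality weights 1874 (797 and 1077). Without VS 1 edgeR called 1611 (602 higher and 1009 lower in Apex), 132 of which met all criteria for naming. Without OR 2 it called 1, Myl7 (edgeR adjusted p 0.0351). Besides Chil3 and Mki67, the largest differences without VS 1 on the higher side were Kif11 (log2 fold change 2.39), Anln, a scaffold of the contractile ring (2.04), and Hoxb4, a positional transcription factor (2.02). On the lower side they were Myl7 (-6.83), Ptgds, a prostaglandin D synthase (-1.63), and Synpo2l, a sarcomeric protein (-1.49). Rps29, a ribosomal protein with pseudogene copies (-1.49), and Cox6a2, a muscle cytochrome c oxidase subunit (-1.48), followed. The omitted VS 1 lay below every Apex library for Ptgds (4.10 CPM), Rps29 (111 CPM) and Cox6a2 (28.5 CPM). It lay within their range for Synpo2l (2.38 CPM) and above them for Myl7 (1.75 CPM). With all libraries the edgeR adjusted p was 0.324 for Myl7 and 0.664 to 0.665 for the others on the lower side. Mitosis genes were higher in Apex in 22 of 22 cases with all libraries (median 0.86, camera 6.8e-15, adjusted p = 0.244 with an estimated correlation), and 4 passed adjusted over the list alone. In the fit on the pair 10 did, and 0 passed over all genes (adjusted p = 0.294 with an estimated correlation). Without VS 1 their median was 1.07, with 11 past over all genes and 18 adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Also without VS 1, 11 of 15 cardiomyocyte genes, 18 of 26 oxidative phosphorylation genes and 19 of 25 ribosomal protein genes passed as lower in Apex (adjusted p = 0.53 with an estimated correlation for each list). Angiogenic and tip cell genes had a median of 0.22 with all libraries (camera 0.0125, fry 0.048, adjusted p = 0.244 with an estimated correlation), and without VS 1 camera gave 0.254.

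In LV against VS, genes of fibroblasts and connective tissue had higher means in LV. Slit3 was at 9.62 ± 1.45 against 3.63 CPM (SD, n = 3, edgeR adjusted p 0.404). C7, a component of the complement attack complex, was at 12.4 ± 6.29 against 1.45 ± 0.854 CPM. Lpar1, a lysophosphatidic acid receptor, was at 5.94 against 1.43 CPM, and Medag, an adipogenesis gene of mesenteric fat, at 8.48 against 2.76 CPM, none past the threshold. All 15 fibroblast genes were higher in LV, with a median log2 fold change of 1.10 (camera 1.1e-11, adjusted p = 0.446 with an estimated correlation). Of these, 9 passed adjusted over the list alone and 0 over all genes, and without VS 1 the list alone gave 1 and all genes 1. Col3a1, the type III collagen chain, was at 162 ± 86.4 against 53.4 ± 4.91 CPM (edgeR adjusted p 0.762).

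With all libraries edgeR called 0 genes between LV and VS (394 at an unadjusted p under 0.05), and 0 in the fit on these 6. DESeq2 called 18, all higher in LV, and voom with sample quality weights 1, Slit3. Without VS 1 edgeR called 613 (213 higher and 400 lower in LV), and 40 met all criteria. The largest on the higher side were Lpar1 (log2 fold change 2.26), Hoxb4 (2.00), Medag (1.63), Has1, a hyaluronan synthase, and Itga8, an integrin of mural cells. On the lower side they were Nrtn, a neurotrophic factor (-1.54), Tuba8, Hhatl, Galns and Rpl3l, the muscle form of a ribosomal protein. The omitted VS 1 went the other way, below every LV library for each of these lower-side genes (for example 3.02 CPM for Tuba8 and 5.01 CPM for Rpl3l). With all libraries their edgeR adjusted p was 0.999. Cardiomyocyte genes had a median of -0.87 without VS 1, where 6 passed over all genes and 14 adjusted over the list alone (adjusted p = 0.671 with an estimated correlation). Without VS 2 instead, the list turned the other way, with a median of 0.0913 (camera adjusted p 0.0244 with the preset correlation). An estimated correlation was not run without VS 2.

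In VS against OR, the matrix gene Spock2 had a higher mean in VS and the muscle gene Tmem182 a lower one. Spock2 was at 25.9 against 12.7 CPM, Tmem182 at 39.2 against 72.1 CPM and Wdfy1 at 24.8 against 8.69 CPM. Pdia5, a disulfide isomerase, was at 8.06 against 14.8 CPM. Hoxb4 (chr11 at 96318267-96321638) was at 1.96 ± 1.10 against 6.38 ± 0.995 CPM (SD, n = 3). All 5 had an edgeR adjusted p of 0.391. Without VS 1, Spock2 (log2 fold change 1.21) and the sarcomere and muscle energy genes Mybpc3 (1.07), Actn2 (1.06) and Ckm (1.04) passed as higher in VS. Hoxb4 (-2.24) passed as lower. VS 1 itself was below every other library for Mybpc3 (34.8 CPM), Actn2 (22.3 CPM) and Ckm (83.4 CPM). The cardiomyocyte list moved with them, with a median of 0.40 without VS 1 and the opposite direction by camera with all libraries. EdgeR called 0 genes with all libraries (952 at an unadjusted p under 0.05), 0 in the fit on these 6, and 8 without VS 1 (7 higher and 1 lower in VS). DESeq2 called 23 (8 and 15) and voom with sample quality weights 9 (4 and 5). Ribosomal protein genes were lower in VS in 25 of 25 cases with all libraries (median log2 fold change -0.34, camera 7.7e-08, adjusted p = 0.716 with an estimated correlation). Without VS 1 their median was -0.0581 and camera gave 0.461, so this difference rested on that library.

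No region had a distinct gene by edgeR with all 12 libraries, a count of 0 for each of Apex, LV, VS and OR. DESeq2 gave Slit3 for LV. It gave 6 genes as distinctly low in VS, the transcription factors Hoxb2, Hoxb4, Hoxb5 and Hoxd8, the retinoic acid synthase Aldh1a2, and Egfem1. It gave Cry1, Oas2 and Wdfy1 as distinctly low in OR. Voom with sample quality weights gave 8 for Apex, 7 high (the division genes Cenpf, Ccna2, Mki67 and Prc1 with Mest, Chil3 and Mpo) and 1 low (Sln). It gave Slit3 for LV and Gbp5, an interferon-induced GTPase, for OR. Without VS 1, edgeR gave Slit3 for LV and 6 genes for VS, among them Mybpc3, Ckm, Actn2 and Tuba4a high and Hoxb4 low. The omitted VS 1 was the lowest of all 12 libraries for Mybpc3 (34.8 CPM), Ckm (83.4 CPM) and Actn2 (22.3 CPM). All distinct genes named here were looked up after the counts were known.

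**Figure D2:**
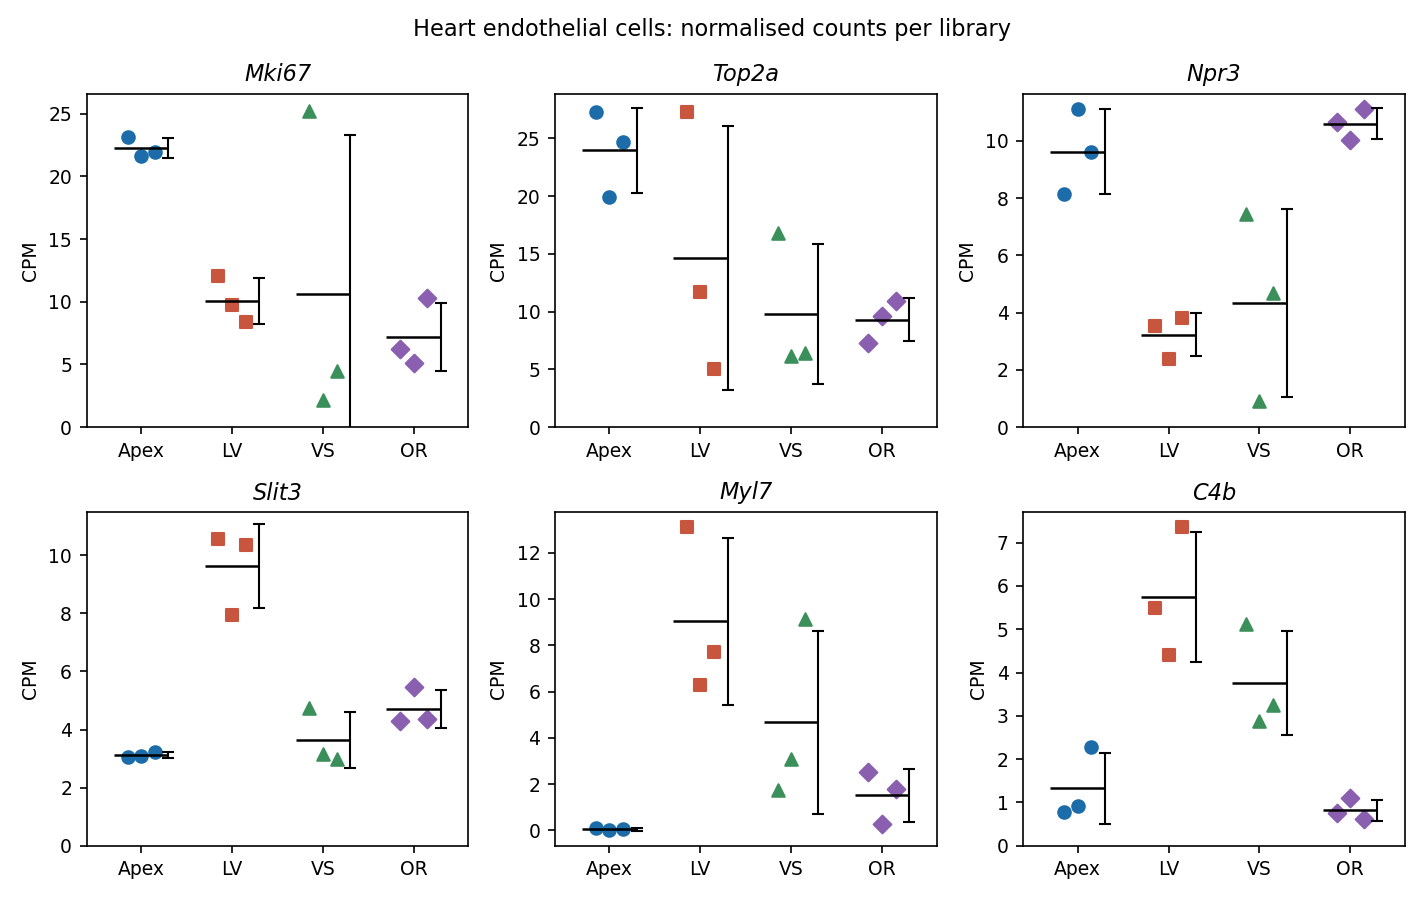
Expression of Mki67, Top2a, Npr3, Slit3, Myl7 and C4b in the heart, in TMM-scaled CPM by region on the x axis. The y axes are linear and start at 0, except that of Myl7. Points are libraries, bars are means and error bars are SD of 3 libraries. Mki67 lies between 21.6 and 23.2 CPM in the 3 Apex libraries, and VS 1 is the only other library at that level, at 25.2 CPM.

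The liver comparison asks how endothelial cells that carry the tdTomato label differ in expression from those without it. Mki67 itself was lower in positive libraries, at 0.388 ± 0.0462 against 1.59 ± 0.297 CPM (SD, n = 3), a log2 fold change of -2.02 ± 0.37 (SE, 4.06-fold). Each positive library lay below every negative one, though at an edgeR adjusted p of 0.276 the gene did not pass. Slfn2, a Schlafen gene of quiescence control in leukocytes, was at 20.7 ± 3.33 against 47.5 ± 3.32 CPM, a log2 fold change of -1.20 ± 0.14. Cmklr1, the chemerin receptor, was at 1.64 against 7.18 CPM, and Trpv4, a mechanosensitive cation channel, at 2.31 against 9.20 CPM. Cdc42se1, an effector of the GTPase Cdc42, was at 43.8 against 73.3 CPM, and Helz2, an interferon-induced helicase, at 35.4 against 55.9 CPM. These 5 also had an edgeR adjusted p of 0.276. Kdr, the main VEGF receptor, was at 2548 ± 62.3 against 1620 ± 453 CPM (0.298 by edgeR), and Top2a had a log2 fold change of -0.70. Slfn2 lies on chr11 at 83065112-83070678.

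Of 13115 liver genes edgeR called 0 with all 6 libraries, with 1872 at an unadjusted p under 0.05. DESeq2 called 683 (99 higher and 584 lower in positive) and voom with sample quality weights 2598 (1269 and 1329). The negative group was split. Fos, an immediate early transcription factor, was at 4715 and 3444 CPM in negative 1 and 2 and at 323 CPM in negative 3, against 410, 242 and 250 CPM in the positive libraries. Gja5, the arterial connexin 40, was at 233, 217 and 17.5 CPM in the negative libraries and at most 12.5 CPM in the positive ones. Stab2, a scavenger receptor of liver sinusoids, was at 637, 433 and 1390 CPM in the negative libraries and 1492, 1496 and 1513 CPM in the positive ones. Clec4f, a lectin of Kupffer cells, was at 12.3, 29.0 and 1898 CPM against 643, 625 and 320 CPM. Mki67 was at 1.92, 1.47 and 1.36 CPM in the negative libraries, all above the 0.336 to 0.424 CPM of the positive ones.

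Without negative 3, edgeR called 4230 of 13414 genes, 2065 higher and 2165 lower in positive libraries, and 995 met all criteria for naming. Negative 3 was picked because its omission changed the calls most, so these calls and their p-values carry that choice. Lower in positive libraries was Atf3, a stress-induced transcription factor (log2 fold change -5.84, edgeR adjusted p 3.0e-06), which was at 11.7 CPM in negative 3 beside a mean of 10.6 CPM in the positive libraries. So were Fosb (-4.38), Sele, the cytokine-induced leukocyte selectin (-4.79), Gja5 (-4.34) and Pcsk5, a proprotein convertase (-4.94). Igfbp3, a binding protein of insulin-like growth factors (-4.19), Stmn2, Rnd1, Alpl, Nfkbiz, P2ry2, Rgs16 and Acta2 completed the lower side. Higher were Cd163, the haemoglobin scavenger receptor of macrophages (5.47) and the myeloid genes Scimp, Cd207, Pld4, Cd300lb, Fpr1, Lair1 and Fgd2. Hbb-bs (5.44), Hbb-bt, Hba-a2, Pira2, Gbp2b and Fam205a3, which have close copies in the genome, were higher too. Fam205a3 had 0 counts in negative 1 and 2 and is given no fold.

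By list, 24 of 24 genes of the dissociation and immediate early response were lower in positive libraries, with a median log2 fold change of -2.26 (camera adjusted p 3.6e-10, adjusted p = 0.465 with an estimated correlation). Of these, 0 passed over all genes and 22 adjusted over the list alone. Genes of portal vessels and capillarised endothelium had a median of -1.60, and 8 passed adjusted over the list alone (adjusted p = 0.465 with an estimated correlation). Genes of sinusoidal endothelium had one of 0.57, with 17 of 19 higher (adjusted p = 0.515 with an estimated correlation). Mitosis genes had one of -0.52 (camera 5.4e-05, adjusted p = 0.465 with an estimated correlation). Kupffer cell and macrophage genes tested as higher in positive libraries while their medians were -0.09 and -0.05 and their means -0.10 and 0.06 (adjusted p = 0.597 with an estimated correlation). Without negative 1 camera gave 0.224 and 0.204 for these lists, and without negative 2 it gave 0.0745 and 0.0572. In all, 28 of 41 lists passed with the preset correlation, 18 without negative 1, and 0 with an estimated correlation or by fry. Without negative 3, all 24 dissociation genes passed as lower over all genes (median -2.74, adjusted p = 0.231 with an estimated correlation), and 13 of 13 Kupffer cell genes as higher (median 4.06, 0.362). Of sinusoidal genes 14 of 19 passed as higher (median 0.81, 0.359), and of portal genes 13 of 17 as lower and 1 as higher (median -2.00, 0.381). Of mitosis genes 5 of 20 passed as lower (0.380). Markers of other cell types moved as well. Fibroblast genes passed as lower at 12 of 15 (median -2.40, adjusted p = 0.351 with an estimated correlation), pericyte and smooth muscle genes at 8 of 12 (median -2.39, 0.231) and hepatocyte genes at 13 of 20 (median -1.26, 0.231). Genes of T, B and NK cells passed as higher at 12 of 14 (median 3.10, 0.332).

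**Figure D3:**
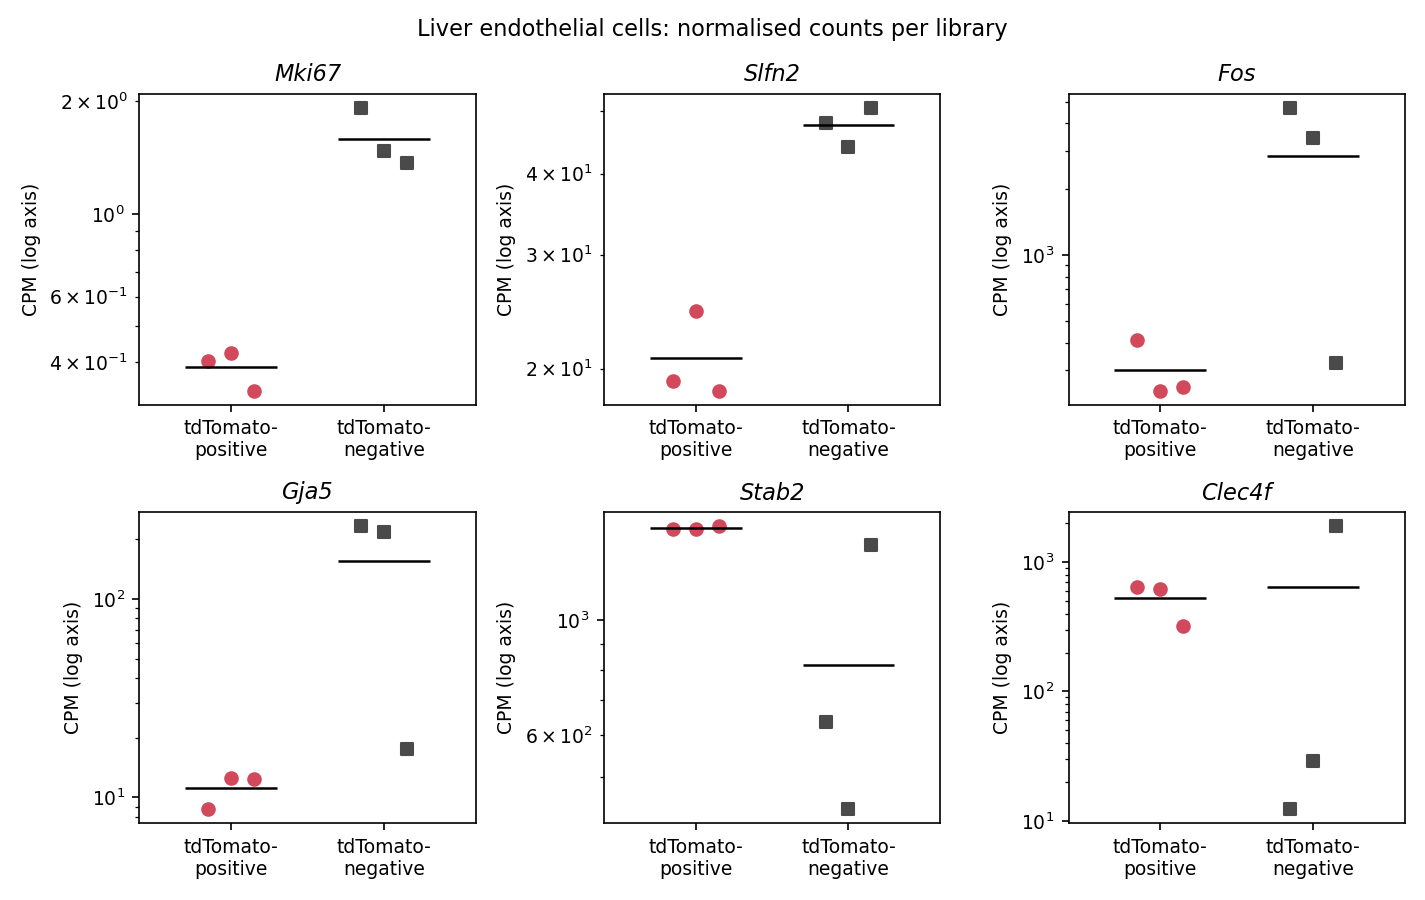
Expression of Mki67, Slfn2, Fos, Gja5, Stab2 and Clec4f in liver tdTomato-positive and tdTomato-negative libraries on the x axis, in TMM-scaled CPM on logarithmic y axes. Points are libraries, and bars are arithmetic means of 3 libraries. Mki67 and Slfn2 separate all 3 positive from all 3 negative libraries, whereas negative 3 lies beside the positive libraries for Fos, Gja5 and Stab2.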

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

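Tests chosen only after the result was seen were voom with sample quality weights, the exact permutation of list levels, and the lists under other scaling, other filters and with a library left out. EdgeR with DESeq2 size factors, no filter or a stricter filter called 0 genes in every heart and liver comparison, as in the report (unadjusted counts there). A fold change minimum only removes calls from the main fit, which had 0, so its 0 calls were fixed in advance. Of 1301 single genes and lists, 1297 kept direction and side of the threshold with DESeq2 size factors and 1286 with no filter. With the stricter filter 1022 did, 11 moved, 10 were weaker and 5 stronger, and the others were no longer tested. The fold change minimum was run on the 1038 single genes only. All of them kept both, which was also fixed in advance, since it keeps the fold changes of the main fit. DESeq2's own test called 87 genes over the 4 regions, 24 for Apex against LV, 19 for Apex against VS, 47 for Apex against OR, 18 for LV against VS, 49 for LV against OR and 23 for VS against OR, with 1 distinct gene for LV, 6 for VS and 3 for OR, and 683 genes in the liver. Voom with sample quality weights called 2908, 38, 1874, 1793, 1, 380 and 9 in the same order, with 8 distinct genes for Apex, 1 for LV and 1 for OR, and 2598 in the liver; its weights were 0.156 for VS 1 and 0.161 for liver negative 3. The replicate number as a block gave 1 gene for Apex against LV, and the fits on a pair alone gave 20 for Apex against LV, 956 for Apex against OR and 462 for LV against OR; leaving out VS 1 alone gave 1, 860 and 375. In the heart 46 list comparisons passed with the preset correlation, 0 with an estimated correlation and 2 by fry. The exact permutation is another kind of test, of each list over the 4 regions together, and 0 of 37 lists passed it. In the liver 28 lists passed with the preset correlation, 0 with an estimated correlation and 0 by fry. With each library left out in turn, the counts ranged from 0 to 1481 over the 4 regions, 0 to 1 for Apex against LV, 0 to 1611 for Apex against VS, 0 to 860 for Apex against OR, 0 to 613 for LV against VS, 0 to 375 for LV against OR and 0 to 8 for VS against OR. Distinct genes ranged from 0 to 1 for LV and 0 to 6 for VS, and stayed at 0 for Apex and OR. Liver genes ranged from 0 to 4230, heart list comparisons from 45 to 58 and liver lists from 18 to 28. The highest heart gene counts came without VS 1 and the highest liver count without negative 3; the lowest liver list count came without negative 1. Some directions turned when a library was left out, given as the lowest and highest log2 fold change. In the liver these were Cd14 (-0.83 and 1.29), Cd5l (-0.86 and 4.06), Clec4f (-0.86 and 4.67) and Csf1r (-0.96 and 4.65), each highest without negative 3, and in the heart Mki67 for LV against VS (-0.60 and 1.59, highest without VS 1). By list median, cardiomyocyte genes turned for LV against VS (-0.87 and 0.0913) and VS against OR (-0.47 and 0.40), dissociation genes for Apex against LV (-0.39 and 0.36), OR (-0.59 and 0.0714) and VS (-0.35 and 0.33), and glycolysis genes for Apex against VS (-0.27 and 0.10) and VS against OR (-0.22 and 0.17). Oxidative phosphorylation genes turned by the test for Apex against VS (-0.57 and -0.069), LV against VS (-0.40 and 0.0529) and VS against OR (-0.44 and 0.0883), and ribosomal protein genes for LV against VS (-0.42 and 0.0778). The dissociation lists turned without Apex 1, and the others without VS 1 or VS 2. Ciita, the activator of MHC class II genes, had a log2 fold change of 4.20 for Apex against VS by voom, against -1.02 to 0.11 by edgeR with a library left out. For the other results that moved, the cause was not tested. Depth limits genes such as liver Mki67, with 9 to 11 counts in each positive library.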

Other observations

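Tests of the neutrophil, erythroid, cardiomyocyte, atrial, handling, vessel-mix and label explanations, and the regroupings of the pairs alone and without negative 3, were chosen only after the results were seen. Over the 4 heart regions the real grouping gave 0 genes and the highest other of 100 regroupings of the 12 libraries gave 11. The distinct genes of Apex, LV, VS and OR gave 0 in the real grouping and 0 in the highest other. A count of 0 is reached by all 100 regroupings whatever the data, so these say nothing about chance. For the heart lists 68 of 100 regroupings gave at least the 46 list comparisons of the real one, and the highest gave 77, so chance cannot be excluded for that count. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. With all 12 libraries in the model the real pairs gave 0 genes and the highest other split gave 0 for Apex against LV, 129 for Apex against VS, 0 for Apex against OR, 492 for LV against VS, 2 for LV against OR and 0 for VS against OR, so that all 10 splits gave as many. The splits with 129 and 492 genes point to a structure of the samples other than region. In the fits on a pair alone, the real split gave 20 genes for Apex against LV and the highest other 0, 956 for Apex against OR and the highest other 0, and 462 for LV against OR and the highest other 4, where 1 of 10 splits gave as many. The fits on Apex and VS, LV and VS, and VS and OR alone gave 0, as did the highest other. The liver gave 0 genes with all 6 libraries and 0 in the highest other, 28 lists against 26, and without negative 3 4230 genes against 0. The last comparison carries the choice of the library left out, which was made by its effect on the calls.

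In the liver, negative 3 lay with the positive libraries rather than with negative 1 and 2. A handling response in negative 1 and 2 alone is argued against as the whole cause, since Kupffer cell genes, which do not belong to that response, lay 2.97 log2 lower in negative 1 and 2 than in any of the other 4 libraries, more than the range of 2.27 among those 4. Another mix of vessel segments and Kupffer cells in negative 1 and 2 may account for part of it: both libraries were above the other 4 for 14 of 17 portal vessel genes and below them for 15 of 19 sinusoidal and 13 of 13 Kupffer cell genes, while over all genes tested they were above for 24.6% and below for 26.9%. Negative 1 and 2 were set apart by these same data, after genes of these lists had shown the split. The counts therefore describe the split and do not test such a mix. A wrong label on negative 3 cannot be told apart from such a mix. Negative 3 lay above all 3 positive libraries for 11 of 19 mitosis genes and below for 2 (33.7% and 34.3% over all genes tested). Of random gene sets, 95% stay at or under 10 above. Such sets ignore that genes of a list may vary together, so the count of 11 cannot decide. Mki67 counts were 10, 11 and 9 in positive against 51, 36 and 35 in negative libraries. In negative 3, however, 13 of 13 Kupffer cell genes were also above all 3 positives, so the sample could carry dividing cells of another type. A difference of the label itself stays open and untested.

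In the heart, mitosis genes were highest in Apex, with a summed level of 197 ± 8.75 CPM against 108 ± 29.5 CPM in the other 9 libraries (SD). Since neutrophil genes such as Mpo and Chil3 were also highest there, dividing neutrophil precursors are a possible explanation. The summed level of the neutrophil list was higher by only 7.96 CPM (15.5 against 7.59), against 89.4 CPM for mitosis genes. That goes against such precursors only if they hold more RNA of the neutrophil list than of mitosis genes. Their content was not measured here, so the test cannot decide. Dividing erythroid cells cannot be told apart from other sources: the summed erythrocyte and platelet level differed by -1181 CPM (SE 754), within a spread of 1673 CPM (SD) between the other 9 libraries that could hide a small share of such cells. Faster division of endothelial cells in Apex remains open as a difference between regions and was not tested.

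Atrial cardiomyocyte genes were lower in Apex than in LV. More RNA of every kind of cardiomyocyte in LV would lower the whole cardiomyocyte list in Apex alike, but its median log2 fold change was -0.13 (SD 0.13 over 15 members) against -1.75 for the atrial list, which argues against it. RNA of atrial cardiomyocytes in the LV, VS and OR samples would keep Myl7 and Sln in 1 ratio. Over the 8 libraries with at least 10 Sln counts the ratio ranged from 1.47 to 3.88. That is more than counting error gives (chi-square test, p 0.00466 from 100000 simulated sets of counts with the same totals). Yet a source with its own variation in the ratio could give that spread. RNA of atrial cardiomyocytes and expression in endothelial cells of the region therefore cannot be told apart.

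The level of each list per library was also permuted over the 4 regions (exact permutation test, 15400 groupings, smallest possible p 6.5e-05). Atrial cardiomyocyte genes had the smallest p, 0.00169 (adjusted over 37 lists 0.0625), with mean levels of 0.60 log2 CPM in Apex, 2.87 in LV, 1.95 in VS and 1.59 in OR. Angiogenic and tip cell genes followed at an exact p of 0.00825 (adjusted 0.145) and VEGF receptors and ligands at an exact p of 0.0118 (adjusted 0.145). Mitosis genes had an exact p of 0.0447 (adjusted 0.264).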
